A study of Escherichia coli with 3 samples.

How the data were processed

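The series holds 3 libraries of Escherichia coli 23S ribosomal RNA, the RNA of the large ribosomal subunit. Per the labels, the RNA came from 27S particles, precursors of the large subunit, of a BLR(DE3) strain that lacks the chromosomal dbpA gene and expresses R331A DbpA. DbpA is a DEAD-box RNA helicase that acts in the assembly of the large subunit. Cells grew at 37 °C to an early density (OD near 0.3), and particles were separated on gradients of 20 to 40%. By their titles, 2 libraries had treatment with CMCT and NaHCO3, and 1 library had NaHCO3 alone. CMCT is a carbodiimide that attaches to the imino nitrogens of uridine, guanosine and pseudouridine. The alkaline NaHCO3 step removes it from uridine and guanosine, while the adduct on N3 of pseudouridine is stable and is read as a substitution or deletion during reverse transcription. Libraries were made by the randomer workflow of mutational profiling, per the labels' protocols, in which random primers start cDNA along the whole RNA.

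Per the file headers, the authors deposited counts for each nucleotide of a 23S sequence of 2909 nucleotides. These are whole-number counts of mutated reads in 16 classes, 4 deletions and 12 substitutions, with the read depth of the nucleotide. The deposited mutation rate is a fraction of reads, the summed classes divided by the depth, and it was recomputed here to within 2.94e-08. The deposited totals give the count of all deletions and of those called unambiguous, and the per-nucleotide classes sum to the unambiguous ones. Deletions whose position is ambiguous were therefore outside the per-nucleotide counts. They were 1580 of 3073 deletions in CMCT library 1, 1207 of 2397 in library 2 and 283 of 684 with NaHCO3 alone. The sources used here do not define ambiguous, and a run of identical bases is an assumed case. No mutated reads were listed as failing the quality cutoff. The aligner, its version, the mutation caller and the reference build are not given in the sources used here.

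Standard E. coli numbers were set from the bases of the 25 modified nucleotides of mature 23S rRNA. All 25 had the listed base when the file position was the standard number plus 2 for 6 sites, from m1G745 to m2G1835, and plus 4 for the 19 sites from Ψ1911 on. A single offset matched at most 19 sites, and any other pair of offsets at most 23. A nucleotide outside these 2 stretches is written with an f and its position in the deposited sequence. In the K-12 MG1655 gene table (ASM584v2), used for names alone, 7 genes (rrlA, rrlB, rrlC, rrlD, rrlE, rrlG and rrlH) encode 23S rRNA. The build behind the files is not stated, so no genome coordinates are given, and the copies' sequences were not used here.

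The list of 10 pseudouridines and 15 other modified nucleotides, the tests and most alternatives were fixed before the data were examined. At each nucleotide, a two-sided Fisher's exact test compared mutated and unmutated reads of each CMCT library with those of the NaHCO3-only library, with Benjamini-Hochberg adjustment within each base. A nucleotide was called raised when, in both CMCT libraries, adjusted p was under 0.05, the rate was at least 2 times that of the NaHCO3-only library and at least 0.5 percentage points above it. The mirrored rule called falls. The design asked for at least 1000 reads in each library. The deepest nucleotide had 956 reads, so 0 nucleotides met that minimum, and the fixed alternative of 100 reads is reported instead. It kept 2826 nucleotides and left out 83. Ratios of rates were undefined where the control had no mutated reads, so 0.1 percentage points were added to each rate, also a fixed alternative. The scaling alternative divided CMCT rates by the level at A and C. It used the rate pooled over A and C, since the median rate at single A and C was 0 in 2 libraries.

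Named positions were all 10 pseudouridines and 15 other modified nucleotides, the 10 called unlisted uridines with the largest difference, up to 5 called positions at each of G, A and C, and up to 5 falls. Uf554 and other unlisted positions named in the text were chosen after their values were seen. Alternatives varied the fold, the difference, the depth minimum, the mutation classes, the adjustment, the scaling and the left-out library, and edgeR's quasi-likelihood test with log depth as offset was also run. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.

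The calling rule was tested on simulated data for the comparison of the CMCT libraries with the NaHCO3-only library, over 2826 nucleotides at the real depths. Of 50 nucleotides raised by 2 percentage points in both CMCT libraries, 1 was called, and 28 of 50 were called at 5 points, 49 at 10 and 50 at 25. Of the 2626 unchanged nucleotides, 0 were called. With edgeR these counts were 9, 42, 50 and 50, with 0 unchanged nucleotides called. Unchanged nucleotides were drawn as independent reads at the same rate in all 3 libraries, without a general rise with CMCT. The simulation therefore does not give the share of false calls in the real data. All these rises were placed in the same simulated set, which loosens the Benjamini-Hochberg adjustment, while 7 nucleotides were called in the real data. The share of rises found can therefore be lower in the real data than in the simulation. The numbering step recovered both offsets in 20 of 20 simulated sequences, in which all listed bases had been planted at those offsets. Insertions and deletions between listed sites were not simulated, so the numbers of unlisted nucleotides between them are unchecked. Rates have exact (Clopper-Pearson) 95% intervals, and a count of 0 is given the limit of 3 reads, which is below the upper end of that interval. These cover counting error alone, since reads without molecular identifiers are not independent molecules.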

Results

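The 3 libraries measured how often reverse transcriptase misread each nucleotide of 23S rRNA from 27S particles, large-subunit precursors of Escherichia coli cells expressing R331A DbpA. Pseudouridines that keep their CMC adduct should be misread more often after CMCT and NaHCO3 (2 libraries) than after NaHCO3 alone (1 library), which the labels give as the control. Mean read depth per nucleotide was 333 in CMCT library 1, 277 in CMCT library 2 and 287 in the NaHCO3-only library, with ranges of 12 to 956, 5 to 793 and 5 to 776. The share of nucleotide reads that were mutated was 0.667%, 0.642% and 0.460%. At the median depth, a count of 0 allows a rate of up to 1.06%, 1.22% and 1.13% in the 3 libraries.

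The CMCT libraries, which the labels number as replicates, differed by no more than the sampling noise. Over the 124 nucleotides with at least 10 mutated reads between them, mutated and unmutated reads gave a chi-square of 119.1 (p = 0.608). Their depth profiles also matched, with a chi-square per degree of freedom of 0.984, against 4.53 and 3.71 for each of them against the NaHCO3-only library. The calling rule used throughout found 0 nucleotides higher and 0 lower in CMCT library 1 than in library 2, and 28 of 2826 nucleotides (0.991%) had an unadjusted Fisher's exact p under 0.05, a value the exact test can seldom reach where few reads are mutated. The 2 libraries were therefore counted as 1 sample, although no other pair of a group was there for comparison, with both rates and their mean given and no standard deviation. No label says that they came from separate cultures. With 1 sample on each side the differences below have no replicate check, and the p-values compare these libraries and not the conditions.

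Of the 10 pseudouridines of mature 23S rRNA, 6 were raised by CMCT: Ψ955, Ψ2457, Ψ2504, Ψ2580, Ψ2604 and Ψ2605. Of these, 5 lie in domain V, which holds the peptidyl transferase centre, and Ψ955 lies in domain II. Mean CMCT rates at the 6 ran from 5.04% to 34.1%, and at 5 of them the NaHCO3-only library had no mutated reads. The other 4, Ψ746, Ψ1911, m3Ψ1915 and Ψ1917, did not pass the test. With p-values adjusted over the list alone, 7 of the 10 were raised, Ψ1917 being the added one.

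The 3 targets of RluC, the synthase for Ψ955, Ψ2504 and Ψ2580, were all raised. At Ψ2580 the rate was 30.8% in CMCT library 1 (86 of 279 reads, 95% interval 25.5 to 36.6%) and 37.5% in library 2 (103 of 275 reads, 31.7 to 43.5%), against 0.466% with NaHCO3 alone (2 of 429 reads, 0.0565 to 1.67%). The ratio of the summed CMCT rate to the control was 73.2 (95% counting interval 20.0 to 609). Ψ955 reached 25% (20.2 to 30.3%) and 25.7% (20.1 to 31.9%), against 0 of 240 control reads. With the control set at its limit of 3 reads (1.25%), the measured mean was at least 20.3-fold higher. Here and below, such a fold takes the measured CMCT mean and leaves out its counting error, so the true fold can be lower. The limit of 3 reads is also below the upper end of the exact 95% interval, which is 1.53% at Ψ955. Ψ2504, in the peptidyl transferase centre, had rates of 8.94% (5.20 to 14.1%) and 8.0% (4.44 to 13.1%) against 0 of 291 control reads, at least 8.22-fold higher. Adjusted Fisher's exact p at these 3 sites was 9.17e-05 or lower in each CMCT library.

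Ψ2457, made by RluE, had rates of 12.5% (7.91 to 18.5%) and 11.03% (6.31 to 17.5%) against 0 of 249 control reads, at least 9.76-fold higher. The neighbours Ψ2604 and Ψ2605 are made by RluF and RluB. Ψ2604 had 5.91% (3.34 to 9.55%) and 4.17% (2.02 to 7.53%) against 0 of 378 control reads, at least 6.35-fold higher, with adjusted Fisher's exact p of 8.63e-05 and 0.00670. Ψ2605 had 5.88% (3.40 to 9.38%) and 7.11% (4.27 to 11.01%) against 0 of 379 reads, at least 8.21-fold higher. Unambiguous deletions made up 81.2% of the mutated CMCT reads at Ψ955, 92.6% at Ψ2580, 94.4% at Ψ2457 and 96.7% at Ψ2504, but 32.0% at Ψ2604 and 29.4% at Ψ2605, which stand next to each other in a run of U. Counting deletions alone ended the calls at Ψ2604 and Ψ2605, where 1.6 of 5.04 and 1.88 of 6.50 percentage points of the difference remained. Counting substitutions alone ended all 6 calls, with differences of 3.44 points at Ψ2604, 4.62 at Ψ2605, 4.60 at Ψ955, 2.06 at Ψ2580, 0.735 at Ψ2457 and 0.279 at Ψ2504.

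**Figure D1:**
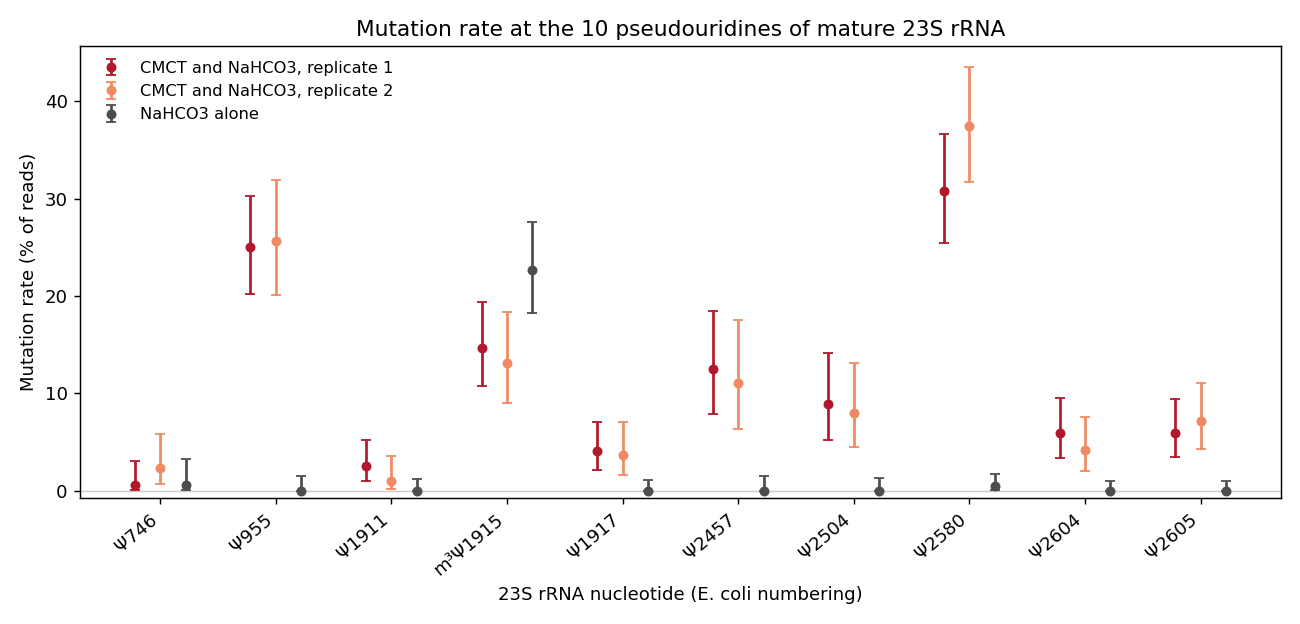
Mutation rate (percent of reads) at each of the 10 pseudouridines in the 3 libraries, with points for the measured rates and bars for exact 95% binomial intervals. The CMCT libraries reach 30.8% and 37.5% at Ψ2580, while at m3Ψ1915 the NaHCO3-only library is the highest at 22.6%.

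RluD makes the 3 pseudouridines of domain IV, in a hairpin that contacts the small subunit in the mature ribosome, and none of the 3 passed the rule in both CMCT libraries. Ψ1917 came closest, at 4.07% (2.12 to 7.0%) and 3.62% (1.58 to 7.01%) against 0 of 329 control reads. Its adjusted Fisher's exact p was 0.00914 in library 1 and 0.0520 in library 2. It was called without library 2, with both CMCT libraries summed, with at least 200 reads, and by edgeR (adjusted p = 0.0232). Ψ1911 had 2.55% (1.03 to 5.19%) and 1.01% (0.123 to 3.60%) against 0 of 311 control reads. At its depth a rate under 3.65% in library 1 or 4.04% in library 2 would not have been called, so a smaller rise was not detectable. m3Ψ1915, whose N3 also carries a methyl group from RlmH, was misread in all 3 libraries, at 14.7% (10.8 to 19.3%) and 13.1% (8.97 to 18.3%) with CMCT and 22.6% (18.2 to 27.6%) with NaHCO3 alone. The rule asked for at least 2 times that control rate, and the stable adduct forms on N3, which is methylated here. The lack of a call at m3Ψ1915 therefore does not tell whether it is a pseudouridine. Its lower CMCT rates had unadjusted Fisher's exact p of 0.0131 and 0.00530 and adjusted p of 0.586 and 0.341. With deletions alone the direction turned, with 6 of 286 and 6 of 221 reads in the CMCT libraries against 0 of 327 with NaHCO3 alone, a difference of 2.41 percentage points in place of -8.73 that was not called.

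Ψ746, made by RluA in domain II, had 0.559% (0.0141 to 3.07%) and 2.31% (0.633 to 5.81%), against 0.592% with NaHCO3 alone (0.0150 to 3.25%). With 179, 173 and 169 reads, rates under 8.38% and 8.67% would not have been called there. No test compared the sites of RluC with those of RluD or RluA.

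Outside the list, 0 of 565 uridines were called raised, which leaves open smaller rises that the rule seldom finds at this depth: in simulated data it called 1 of 50 rises of 2 percentage points. Summed over these uridines, the mutation rate was 0.739% and 0.741% with CMCT and 0.471% with NaHCO3 alone. At an unadjusted Fisher's exact p under 0.05 in both libraries, 12 of all 579 uridines were higher with CMCT and 1 was lower, and edgeR called 7 uridines, all on the list. The largest mean difference among unlisted uridines was 4.99 percentage points, at Uf554, a position at 18.8% with NaHCO3 alone. The share of raised nucleotides was 1.04% for U (6 of 579) and 0.0736% for A and C together (1 of 1359), bases with no imino nitrogen for CMCT to react with (Fisher's exact p = 0.00365). Of 888 G, which CMCT also modifies, 0 were raised. Unadjusted, 2 G, 1 A and 1 C were higher in both CMCT libraries and 1 G was lower. The mirrored rule called 0 falls at any base.

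As a group, the listed pseudouridines stood above the other uridines. The median difference between the mean CMCT rate and the control was 5.77 percentage points at the 10 listed sites and 0.242 at the 569 other uridines. On the log2 scale with 0.1 percentage points added, the medians were 5.80 and 1.16, a difference of 4.64 (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). With control counts of 0 set at 3 reads, the median of the list was 2.85. Of the 10 sites, 8 lay above the 95th percentile of the other uridines. Nucleotides of 1 molecule are not independent replicates, so this ranks sites within these libraries.

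**Figure D2:**
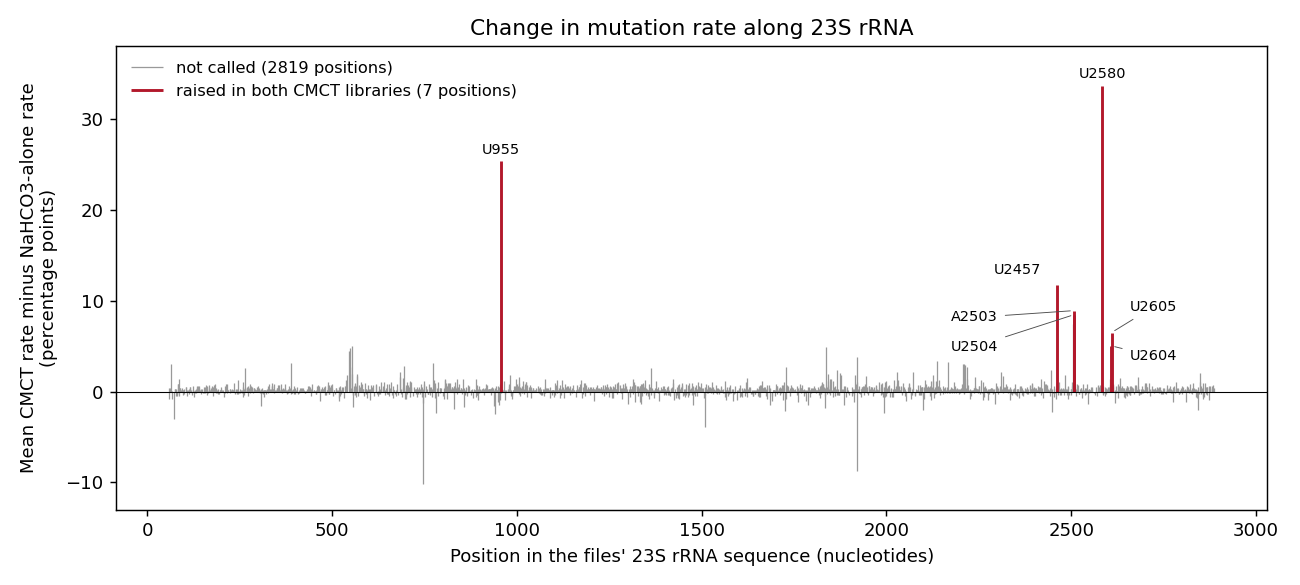
Mean CMCT rate minus the NaHCO3-only rate (percentage points) at 2826 nucleotides, against position in the deposited 23S sequence (nucleotides). The 7 raised nucleotides are in red, with U2580 the highest at 33.7 points, and the nucleotides not called are in grey.

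The call outside pseudouridine was m2A2503, a 2-methyladenosine made by RlmN, next to Ψ2504. It had 6.70% (3.51 to 11.4%) and 11.1% (6.82 to 16.8%) against 0 of 290 control reads, at least 8.61-fold higher, with adjusted Fisher's exact p of 0.00558 and 2.50e-06. Deletions made up 90.3% of its mutated CMCT reads. Fewer than 200 reads covered it in each CMCT library, so it was not among the nucleotides tested at that minimum.

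Of the 15 other modified nucleotides, 5 exceeded the 95th percentile of unlisted nucleotides of the same base in all 3 libraries: m1G745, m2G1835, m7G2069, D2449 and ho5C2501. m1G745, methylated on its pairing edge by RlmA, was misread in 54.2% (46.6 to 61.6%) and 54.4% (46.6 to 62.0%) of CMCT reads and 64.5% (56.7 to 71.7%) of NaHCO3-only reads. m2G1835, made by RlmG, had 56.0%, 59.3% and 52.7%, and 93.3% of its mutated reads over the 3 libraries were G-to-C changes. m7G2069, made by RlmKL, had 11.3%, 16.1% and 11.5%, and D2449, dihydrouridine, had 11.6%, 10.8% and 11.7%. By group, this held for 2 of 5 nucleotides altered on the pairing edge, 3 of 7 altered elsewhere on the base and 0 of 3 methylated on the ribose. These values are ranks within libraries and were not tested. At m1G745, m2G1835, m7G2069 and D2449, Fisher's exact adjusted p for CMCT against NaHCO3 alone was 1 in each CMCT library.

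ho5C2501, hydroxylated by RlhA, was at 11.9% (7.50 to 17.6%) and 6.55% (3.31 to 11.4%) with CMCT and 1.72% (0.562 to 3.98%) with NaHCO3 alone. Its adjusted Fisher's exact p was 0.00512 in library 1 and 1 in library 2, so it was not called. It was called without library 2, with both CMCT libraries summed, and by edgeR (adjusted p = 0.0312). m2G2445, the other site of RlmKL, had 3.66%, 1.44% and 4.81% and missed the 95th percentile in CMCT library 2, where it stood at percentile 94.0. Cm2498 had 1.69%, 1.81% and 0.692%. m5U747 and Gm2251 had 0 mutated reads in the 3 libraries, which allows up to 1.65%, 1.72% and 1.78% at m5U747 and 0.752%, 0.946% and 1.02% at Gm2251. At the remaining 5, m6A1618, m5U1939, m5C1962, m6A2030 and Um2552, no library exceeded 0.985%. Um2552 lies in the hairpin that DbpA binds, and had 0.722%, 0.692% and 0.238%.

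**Figure D3:**
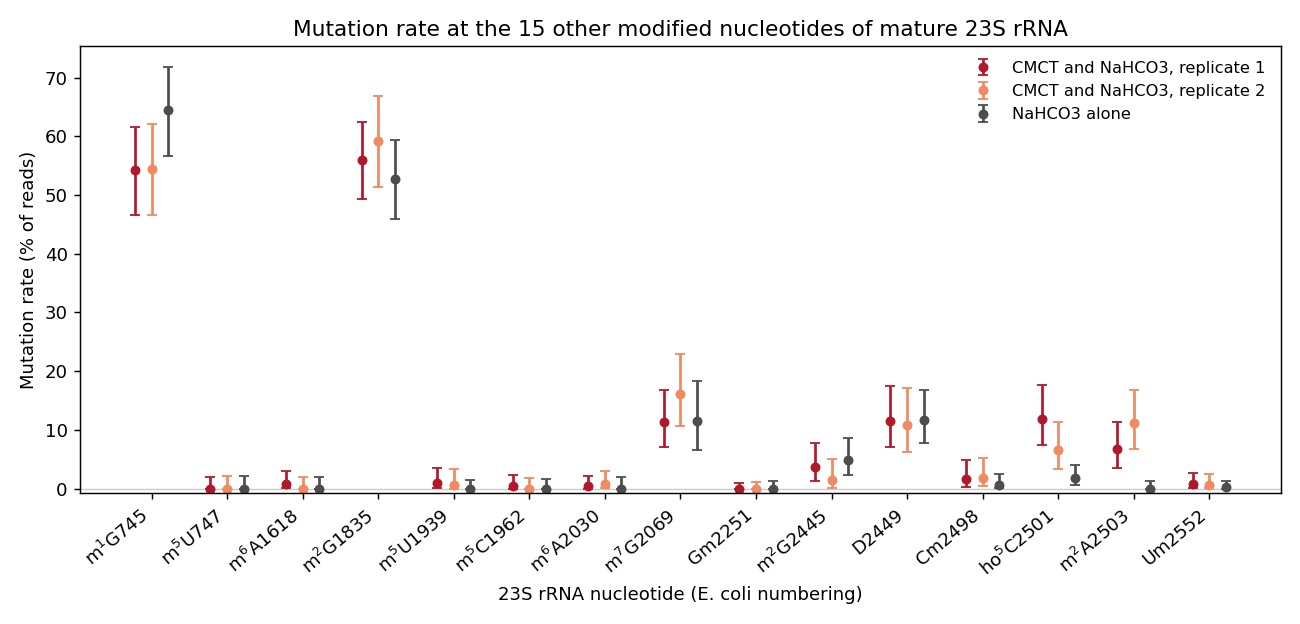
Mutation rate (percent of reads) at each of the 15 other modified nucleotides in the 3 libraries, with points for the measured rates and bars for exact 95% binomial intervals. m1G745 and m2G1835 lie between 52.7% and 64.5% in all 3 libraries, and m2A2503 has 0 mutated reads with NaHCO3 alone.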

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

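Deletions whose position was ambiguous are counted in the deposited totals and lie outside the per-nucleotide values used above. They were picked out as a signal in unused data above the control. They made up 0.163% of nucleotide reads in CMCT library 1 (1580 deletions, exact 95% interval 0.155 to 0.171%) and 0.150% in CMCT library 2 (1207 deletions, 0.142 to 0.159%). With NaHCO3 alone they made up 0.0339% (283 deletions, 0.0301 to 0.0381%). The totals do not place these deletions on nucleotides, so how many of them belong to Ψ746, Ψ2604 or Ψ2605, which each stand beside another U, was not analysed here.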

How the results depend on the processing

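Over all results that answer a comparison, 79 alternative values kept their direction and side of the threshold or stayed within 1.5 times the count, 3 moved and 1 lost its test. With substitutions alone, 0 uridines and 0 listed pseudouridines were raised, and the difference in share between U and A and C was 0 percentage points (Fisher's exact p = 1); 81.2 to 96.7% of mutated CMCT reads at 4 of the sites were deletions, and the listed sites still stood above other uridines (log2 difference 2.74, permutation p = 3e-05). At the 99th percentile, 3 other modified nucleotides stood out instead of 5, a stricter limit by construction. Otherwise the count of raised uridines ran from 4 (deletions alone) to 7, and was 6 and 7 without CMCT library 1 and 2. Without library 2, Ψ1917 and C2501 were also called. At the 7 called sites, 93 alternative values kept the call, 9 lost it and 0 changed sign. The fold, difference and scaling settings could not end these calls. The control there was 0 or 0.466%, Fisher's test alone asked for rates of at least 3.15%, and scaling left the tested counts unchanged. At the 18 sites not called, 245 values stayed so and 7 gained a call, while 7 changed sign: with deletions alone m3Ψ1915 (-8.73 to 2.41 percentage points), D2449 (-0.549 to 2.45) and C2501 (7.48 to -0.125), with scaling to A and C m2G1835 (4.92 to -8.32) and m7G2069 (2.17 to -0.930), and without library 2 m7G2069 (to -0.248) and Ψ746 (0.844 to -0.0331). The depth alternatives of 1000 and 5000 reads left 0 nucleotides and gave no value. Depth minimums of 50 and 200 reads, summing the CMCT libraries and the rates of unlisted nucleotides by base were chosen after seeing the data. Their values count among the 79. With 200 reads Ψ2457 and Ψ2504 dropped out untested. edgeR's spread is that between CMCT libraries counted as 1 sample. The rule missed many small rises at these depths: 28 of 50 simulated rises of 5 percentage points were found, and 1 of 50 of 2 points. At the same depths edgeR found 42 and 9, and depth was not varied. These shares can be too high for the real data, since many nucleotides were raised at once in the simulation. No paired analysis was possible because there is 1 NaHCO3-only library, whose label carries no replicate number.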

Other observations

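All tests in this part were chosen after the result was seen, except the removal of the 10 uridines with most deletions. Away from the listed sites, CMCT went with more deletions at each base. At the 565 unlisted uridines, deletions rose from 0.0332% of reads with NaHCO3 alone to 0.208% and 0.199% in the CMCT libraries, a mean of 6.12-fold (Fisher's exact p = 6.79e-49 or lower). The mean rise was 2.98-fold at G, 2.48-fold at A and 1.61-fold at C. Without positions over 5% in the control it was 6.05-fold at U, 4.29-fold at G, 3.82-fold at A and 1.99-fold at C, so the value at A moved by more than 1.5 times. Substitutions rose less, by 1.18-fold at C to 1.32-fold at G. Isolated uridines had 0.265% and 0.258% deletions with CMCT and 0.0444% with NaHCO3 alone. Uridines in runs of U, where a deletion may be ambiguous and so left out of the counts, had 0.0811% and 0.0658% with CMCT and 0.00933% with NaHCO3 alone. The lower level in runs thus held in the control too.

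A uniform rise of the deletion level at all bases was argued against: the fold at U was 3.03 times that at A and C (permutation p = 0.00073), and 2.18 times (p = 0.00764) without positions over 5% in the control. A and C differed, with 3.82-fold and 1.99-fold against 6.05-fold at U without those positions, and U was not tested against A alone. A few strong unlisted sites were argued against too, since the ratio was 2.93 without the 10 uridines with the largest rise. Without the 10 uridines with most CMCT deletions it was 4.14, above the 3.03 of all unlisted uridines. Those 10 had thus risen by a smaller fold than the rest, so their removal says little about strong sites. Those 10 uridines with most deletions did hold 16.9% of them, above the highest share of 9.92% in 1000 draws from a single rate. CMC left on some U and G by the alkaline step may account for the rise, and stays open: the fold at G was 1.48 times that at A and C (permutation p = 0.137) but 1.20 times that at A alone (p = 0.594), and 1.12 times (p = 0.717) without positions over 5% in the control, so an excess at G over A was not shown. The design gives no biological explanation that could be tested.

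m2A2503 rose as much as its neighbour Ψ2504, with a ratio of 1.05. It had 28 deletions in 350 CMCT reads, where the rate of unlisted A gives 0.355, a gap that follows from its choice as the A that was called and tests no explanation. Deletions written a nucleotide 5′ of the adduct at every raised pseudouridine were argued against. The ratios use all mutated reads and not deletions alone. At the 4 other sites with an unlisted 5′ neighbour, the median ratio was 0.0270. The upper limit was under 0.25 at 3 of them, Ψ955, Ψ2457 and Ψ2580, where deletions made up 81.2 to 94.4% of mutated CMCT reads. This criterion was rewritten after the ratios were seen, since the first asked that the highest ratio be under 0.25. The highest ratio of the 4 was 0.356, at G2603 beside Ψ2604. Ψ2605 was left out because its 5′ neighbour Ψ2604 was itself called. The ratio there was 0.775, so misplaced reads could not be judged at that pair. Misplaced deletions at m2A2503 and Ψ2504 alone could still account for the call at m2A2503 and were not tested, and no biological explanation was tested.

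In all 3 libraries, 23 unlisted nucleotides were misread in more than 5% of reads, from 7.58% to 66.3% with NaHCO3 alone, among them G1723, Cf264 at 50.2% and Cf357 at 47.6%. Copies of the 23S rRNA gene that differ from the reference may account for them: the 12 that lie within 15 nucleotides of another form 4 groups with nearly equal rates (chi-square 2.02 on 24 degrees of freedom), such as U2203, G2205, C2209 and G2215 at 9.01% to 9.70% with NaHCO3 alone, and 11.4% to 12.1% and 12.7% to 13.3% in the CMCT libraries. Modified nucleotides misread independently of each other were argued against for these 12, whose rates were closer than separate draws allow (lower-tail chi-square p = 9.04e-10). For the 11 isolated positions gene copies and modified nucleotides cannot be told apart, since the leading class held at least 96.6% of mutated reads there and 93.3% at m2G1835, a known modification. At the other listed nucleotides with a high rate it held less: 42.4% at m1G745, 44.3% at m7G2069, 54.2% at D2449 and 86.5% at ho5C2501. Reads from a related rRNA would also give equal rates and were not tested.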
